A study of Mus musculus with 4 samples.

How the data were processed

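Acetylation of lysine 5 of histone H2B (H2BK5Ac), a mark of active promoters and enhancers, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse trophoblast stem (TS) cells. TS cells are cultured stem cells of the placental lineage. The series holds 4 samples, 1 for each group. TSWT cells were wild type and carried the empty pLKO vector. TSKI4 cells carried a lysine-to-arginine knock-in that inactivates the kinase MAP3K4, with the same vector. TSKI4 HDAC6 sh2 cells carried the knock-in and a short hairpin RNA against HDAC6, a deacetylase. The fourth sample was an input library of TSWT chromatin without antibody, and it was not analysed here. Comparisons with input, subtraction of input and random gene lists matched on input were therefore not run.

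Per the labels, fixed and sonicated chromatin was precipitated with an H2BK5Ac antibody and the libraries were amplified by PCR and sequenced from a single end. Reads were aligned to the mouse genome build mm9 with Bowtie 1.1.2, per the submitters' processing notes. The authors deposited a single table of RPM values (reads per M reads in the library), with 35801 rows, each a RefSeq transcript of the mm9 refFlat annotation, and 3 value columns. The column named for the wild type was taken as the TSWT ChIP library and not as its input, because the remaining columns name lines that had only a ChIP library. Read filters and the kind of library total are not given in the sources used here. For the counted window, the name of the deposited table holds only the label 10 kb. Transcripts with the same start had the same value. Deviations of neighbouring windows from the local level were correlated across pairs of starts, at 0.963 for starts 0 to 4 kb apart and 0.0692 for starts 20 to 24 kb apart, as for windows of 20 kb (10 kb on each side of the start). That width is an inference from the values, and a value covers the promoter region and whatever else lies in the window. Values of genes whose windows overlap rest partly on the same reads, so loci (groups of genes with overlapping windows) are given beside genome-wide counts of genes. Gene starts were compared with the GENCODE annotation of NCBIM37, the same assembly. Of 20644 gene symbols found there, 97.2% had a start within 1 kb. Coordinates are given as in the deposited table, counted from 1.

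In each library, 100% of the RPM values were whole multiples of the value of 1 read, within 0.02 reads, so the number of reads behind each value was recovered. The library totals implied by that step were 72.2 M reads for TSWT, 82.5 M for TSKI4 and 76.3 M for TSKI4 HDAC6 sh2. The median gene region held 737, 798 and 742 reads. By a normal approximation this gives a 95% counting error of about 7.22%, 6.94% and 7.2% on either side. Intervals of RPM values are exact Poisson intervals at 95%. Intervals of ratios are exact conditional binomial intervals at 95%. All intervals and floors cover counting error only, since PCR copies are not independent molecules. A count of 0 reads was treated as up to 3 reads, the floor.

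For each of 24408 gene symbols the row with the highest mean over the 3 libraries stood for the gene. Genes with a mean below the 25th percentile (7.27 RPM) were left out, which left 18306. Log2 ratios were computed on RPM plus a pseudocount of 0.995 RPM (0.1 of the median), which understates the change of low genes. Each group had 1 library, so there was no replicate check and no p-value. A gene was called higher or lower when its ratio on that scale was at least 1.5-fold. Such calls compare 2 libraries and not conditions. Printed ratios are RPM ratios without the pseudocount, and log2 values include it. The comparisons were TSKI4 against TSWT, TSKI4 HDAC6 sh2 against TSKI4, and TSKI4 HDAC6 sh2 against TSWT, with a count of genes that passed the rule in opposite directions in the first 2.

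The size rule, the filter, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The design allowed for a table of counts or of normalized values, and the deposited RPM values were used as they stood, with the count-based interval rule as an added alternative. Named genes were the 10 highest and 10 lowest ratios in each comparison among called genes with a mean above the median of all genes (9.95 RPM or more), leaving out microRNA, snoRNA and unnamed gene models. Genes with overlapping windows were named together. Map3k4 and Hdac6 were always given, and up to 2 members with the highest and 2 with the lowest ratio were taken from each list. The 25 lists were tight junctions and polarity, adherens junctions with desmosomes and keratins, epithelial regulators, mesenchymal genes, extracellular matrix and integrins, trophoblast stem cell factors, differentiated trophoblast, FGF and ERK response, MAP3K4 signalling, histone deacetylases and sirtuins, acetyltransferases and chromatin regulators, actin cytoskeleton and migration, imprinted genes, interferon response, cell cycle, housekeeping genes, Hox genes, olfactory and vomeronasal receptors, ribosomal proteins, mitochondrial complex I and replication-dependent histones, with markers of pluripotent cells, of primitive endoderm, of fibroblasts and of blood, neural and muscle cells. The median log2 ratio of a list minus that of all genes (the relative median) was ranked among 10000 random lists of the same size matched on mean signal in 20 bins. A list stood apart when its percentile was under 2.5 or over 97.5, and 5% of lists of scattered genes would do so by chance. Members of clustered lists (Hox, histone and receptor genes above all) are not independent, so their percentiles overstate rarity. All lists were therefore also ranked with 1 value per locus, a choice made after the data were seen.

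Because ratios shifted along chromosomes, an alternative was added after the data were seen. It subtracted from each log2 ratio the median ratio of the gene regions within 5 Mb (1 per 20 kb, skipping 100 kb around the gene, with at least 10 neighbours). These centred ratios could be computed for 18160 genes, and counts and list medians are given in both forms. The named-gene rule was applied to them as well. Other alternatives added then were the 11 chromosomes without a shifted block, which hold 8854 of the genes, centring in bins of GC content, centring on neighbourhood and signal together, centring without 3 short blocks, and the interval rule on recovered reads. The alternatives fixed earlier covered scaling, the pseudocount, the filter, the size rule, the choice of row and the sex chromosomes.

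The calling steps were tested on simulated reads for the TSKI4 against TSWT comparison over 18306 genes, with a shifted chromosome built in. As deposited, 95.6% of genes changed 1.75-fold, 100% of those changed 2-fold and 0% of those changed 1.3-fold were called. After centring, 92% of the genes changed 1.75-fold were called. Of 985 unchanged genes on the shifted chromosome, 20.3% were called as deposited and 0% after centring, and 0 of 17121 unchanged genes elsewhere were called in either setting. Random lists stood apart in 4.25% of 400 trials, and the ratio interval held the true ratio in 96.1% of 2000 trials. The simulated reads held counting noise, the built-in changes and 1 evenly shifted chromosome only. They held no shifted segments, short blocks, trend with signal or spread between cultures, so these rates do not cover such effects. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.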

Results

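H2BK5Ac was profiled in 3 ChIP libraries, 1 each for wild-type cells (TSWT), knock-in cells (TSKI4) and knock-in cells with the HDAC6 hairpin (TSKI4 HDAC6 sh2). The deposited values were read densities in a window around each gene start, on build mm9, in reads per M library reads (RPM). The libraries implied totals of 72.2 M, 82.5 M and 76.3 M reads, and the median gene region had 10.2, 9.67 and 9.72 RPM. With 1 library per group no difference could be set against a spread between replicates, and all intervals below cover counting error only. Housekeeping gene regions (29 genes) had a median of 20.97 RPM in TSWT, against 5.79 RPM in 1346 olfactory and vomeronasal receptor regions, whose genes serve sensory neurons. That ratio was 3.62 in TSWT, 2.61 in TSKI4 and 2.57 in TSKI4 HDAC6 sh2.

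The engineered genes were examined first. Map3k4, which encodes the kinase inactivated in TSKI4 cells, lies on chromosome 17 (12420487 to 12511526). Its region had 11.7 RPM in TSWT, 13.2 in TSKI4 and 11.2 in TSKI4 HDAC6 sh2, and TSKI4 was 1.13 times TSWT (1.04 to 1.24), inside the 1.5-fold rule. A point mutation need not alter the mark at its own gene, so this value does not check the label. Hdac6, the target of the hairpin, lies on the X chromosome (7507248 to 7525015) and had 12.9, 21.1 and 11.9 RPM. It was 1.64 times TSWT in TSKI4 (1.51 to 1.77), and 0.562 times TSKI4 in TSKI4 HDAC6 sh2 (0.518 to 0.609). Both differences followed the rest of the X chromosome. Relative to neighbouring genes the log2 ratio was 0.02 in the first step and −0.06 in the second. A hairpin acts on the RNA, so the mark at the gene does not measure the knockdown.

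The first comparison set the knock-in cells against wild type, with 1 library each. These lines also differed in Y reads and in shifts along chromosomes, as described below. A difference here therefore cannot be assigned to the loss of MAP3K4 kinase activity. H2BK5Ac was lower in TSKI4 at 1505 gene regions (975 loci) and higher at 257 (202 loci) of 18306. Among regions with a mean of at least 9.95 RPM, the lowest ratio was at Sall1, a zinc-finger transcription factor gene on chromosome 8 (91551143 to 91568061), which fell from 32.6 to 5.48 RPM, 0.168 times TSWT (0.152 to 0.186). The highest of these was at Eda2r, the X-linked gene of an ectodysplasin receptor, which rose from 6.15 to 23.6 RPM. No input was subtracted, and olfactory and vomeronasal receptor regions had medians of 5.79, 6.27 and 6.60 RPM in TSWT, TSKI4 and TSKI4 HDAC6 sh2. Sall1 in TSKI4 and Eda2r in TSWT were near or below those levels, so their ratios do not measure the mark alone. The same holds for other values near those levels. Tight junction and polarity genes were among those that fell, including Cgn and Pard6b. The keratin genes Krt18 and Krt7 also fell, but their list did not stand apart. Hoxb13 and Grm6 rose more than 2-fold. Ratios also shifted along chromosomes, so counts, list medians and part of the genes are also given after centring on neighbouring genes. Ratios without such a value are as deposited. After centring Pard6b and Krt18 still passed the rule (−0.74 and −0.60), while Cgn and Krt7 did not (−0.58 and −0.47).

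Among the genes that fell most, Lemd1 and Cdk18 on chromosome 1 went from 34.0 to 8.398 RPM and from 32.0 to 11.4 RPM. Card10, a scaffold of NF-κB signalling, and its neighbour Cdc42ep1, an effector of the GTPase CDC42, fell from 38.7 to 12.2 RPM and from 33.7 to 11.1 RPM on chromosome 15. Fabp3, a fatty acid-binding protein gene on chromosome 4, fell from 40.96 to 14.8 RPM. Kifc3 (a kinesin), Def8 and the adjacent pair Tmem59l and Crlf1, all on chromosome 8, were at 0.354, 0.380, 0.371 and 0.374 times TSWT. Dag1, which encodes dystroglycan, was at 0.344 times TSWT and lies in a low block of chromosome 9 described below. After centring, Sall1 (−1.77), Lemd1 (−1.40), Card10 (−1.38), Cdc42ep1 (−1.31), Dag1 (−1.26) and Fabp3 (−1.26) had the 6 lowest log2 ratios among regions above that mean. Elf1, Wbp4 and Naa16 on chromosome 14 (−1.20, −1.20 and −1.17), in another low block, and Zfp572 with the adjacent Sqle, a cholesterol synthesis gene (−1.18 and −1.07), came next. Zfx on the X chromosome had 11.9 RPM in TSWT and 15.7 in TSKI4, and was low only relative to its neighbours (−1.16).

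Of the 10 highest loci above the same mean, 6 were on the X chromosome. They held Eda2r, Stard8 (13.3 to 41.9 RPM, a GTPase-activating protein of the RHO family), Yipf6 (7.27 to 21.7), Las1l (9.36 to 23.6, a ribosome biogenesis factor), Sash3 (11.8 to 29.3) and Glod5 (8.62 to 21.4). The autosomal ones were Grm6, a glutamate receptor gene, with the adjacent Zfp879 (10.4 to 34.7 and 10.5 to 27.6 RPM), Antxrl (6.51 to 16.9), the homeobox gene Hoxb13 (11.7 to 27.7) and Tmem98 (11.4 to 26.8). After centring, Grm6 (1.79), Zfp879 (1.47), Antxrl (1.33) and Hoxb13 (1.296) led. They were followed by the cyclin-like gene Ccnjl (1.24, 20.9 to 36.8 RPM), the transcription factor gene Tcf15 (1.13, 11.4 to 19.8), Elmo1 (0.91, 8.03 to 15.3), Pilra (0.88, 10.8 to 19.6), Eda2r (0.87), Dhrs3 (0.85, 8.60 to 14.7) and Olfr90 (0.82, 9.20 to 15.4). Las1l changed direction after centring (−0.24), since its neighbours on the X chromosome were raised further.

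**Figure D1:**
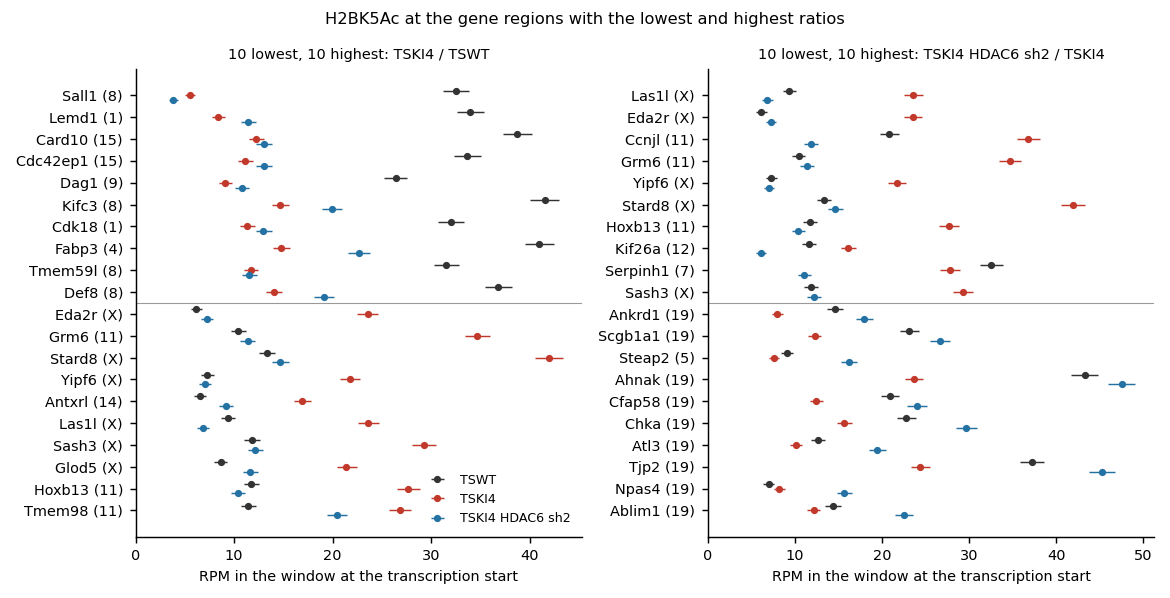
H2BK5Ac (RPM, x axis) in TSWT (black), TSKI4 (red) and TSKI4 HDAC6 sh2 (blue) at the loci with the 10 lowest and 10 highest ratios among named genes with a mean of at least 9.95 RPM, with the chromosome in brackets, for TSKI4 against TSWT (left) and TSKI4 HDAC6 sh2 against TSKI4 (right). Bars are 95% counting intervals of 1 library each, and the first gene of a locus stands for it. Sall1 goes from 32.6 to 5.48 RPM on the left, and 9 of the 10 highest on the right are on chromosome 19.

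Median log2 ratios of TSKI4 to TSWT were −0.48 on chromosome 1 (1226 genes), −0.57 on chromosome 8 (1000 genes) and 0.53 on the X chromosome (256 genes), against −0.11 over all genes. Relative to all genes these were 0.772, 0.723 and 1.55 times. Chromosome 11 was split. Relative to genes of like signal, its 10-Mb bins were at −0.45 to −0.32 over the first 50 Mb and at 0.13 to 0.59 beyond. Chromosome 2 was low in bins from 90 to 160 Mb (−0.42 to −0.30) and chromosome 15 from 80 Mb on (−0.26 to −0.20). Chromosome 3 was at −0.27 to −0.11 in bins from 90 to 150 Mb. On the X chromosome the bin from 70 to 80 Mb was at 0.13 and the others at 0.40 to 0.89. Chromosomes 1, 2, 4, 5, 8, 11, 15, 19 and X had a shifted 20-Mb block in at least 1 of the 3 comparisons, 4, 5 and 19 only in those with TSKI4 HDAC6 sh2. With Y, which has 0 tested genes, these 10 held 51.6% of the genes, 85.0% of the lower and 89.5% of the higher calls. Chromosome 8 alone held 475 of the lower genes, chromosome 1 held 383, and the X chromosome held 111 of the higher. Windows with low signal (2 RPM up to the filter) shifted with the tested genes, by −0.44 on chromosome 1, −0.49 on chromosome 8 and 0.68 on the X chromosome relative to the other chromosomes. After centring, 248 genes (176 loci) were lower and 78 (70 loci) higher.

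**Figure D2:**
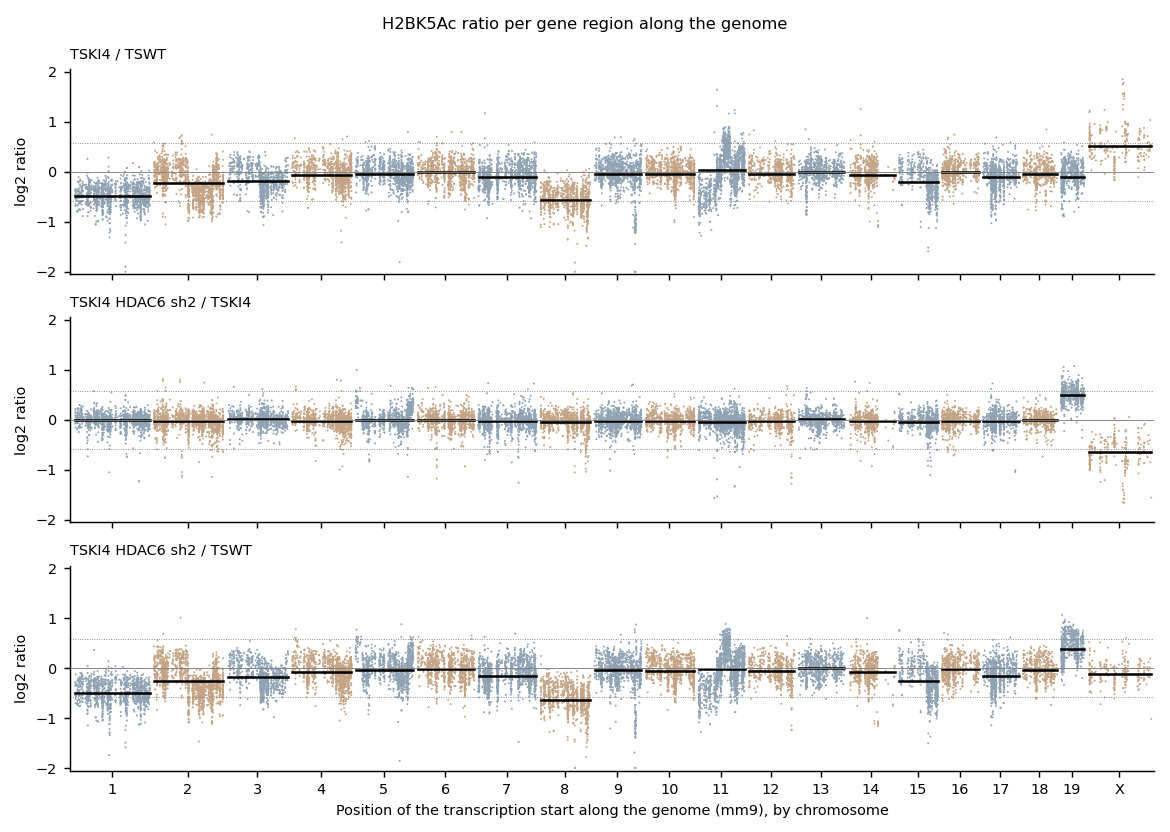
Log2 ratio of H2BK5Ac per gene region (y axis, points, drawn at ±2 where beyond) against position along chromosomes 1 to 19 and X (x axis, mm9) for the 3 comparisons. Black lines are chromosome medians and dotted lines the 1.5-fold rule. Chromosomes 1 and 8 lie low in TSKI4 against TSWT (medians −0.48 and −0.57), and chromosome 19 and the X chromosome lie apart in TSKI4 HDAC6 sh2 against TSKI4 (0.50 and −0.65).

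Sharper changes stood inside this pattern. On chromosome 9, all 88 genes from Rbm6 to Setd2 (starts from 107775150 to 110435101, 53 loci) had a ratio below the median of their neighbours. Their median fell from 11.6 RPM in TSWT to 5.48 in TSKI4, 0.557 times the neighbours' ratio, and was 5.42 in TSKI4 HDAC6 sh2. On chromosome 14, 15 genes from Zfp957 to Olfm4 (79647174 to 80400109) had medians of 9.70, 4.96 and 4.68 RPM. On the X chromosome, 24 genes from Spin4 to Pja1 (92222021 to 96666074) had medians of 3.37, 12.9 and 4.21 RPM, 1.79 times the rise of their neighbours. Eda2r, Stard8, Yipf6 and Las1l lie in this block. These block edges were chosen after their values were seen. Of the genes called after centring, 48 of 248 lower and 5 of 78 higher ones lie in the 3 blocks.

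Inside the chromosome 9 block, the region of Rhoa, the gene of the actin-regulating GTPase RHOA (108208491 to 108240274), had almost no reads in either TSKI4 line. It had 1754 reads (24.3 RPM) in TSWT, 18 reads (0.218 RPM, 0.129 to 0.345) in TSKI4 and 0 reads in TSKI4 HDAC6 sh2. TSKI4 was thus at 0.898% of TSWT, and TSKI4 HDAC6 sh2 was at least 618-fold lower than TSWT at a floor of 3 reads (0.0393 RPM). The overlapping windows of Nicn1, Amt and Tcta, named after their values were seen, had 15.2, 22.4 and 24.3 RPM in TSWT and 0.121, 0.194 and 0.218 RPM in TSKI4. The flanking Dag1 and Gpx1 kept 9.09 and 10.5 RPM. These 4 windows were the only ones of 22697 off the Y chromosome, with at least 4 RPM in TSWT, that were under 10% of TSWT in TSKI4. The same number was found in TSKI4 HDAC6 sh2, and 0 windows were that low in TSWT relative to either TSKI4 line.

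**Figure D3:**
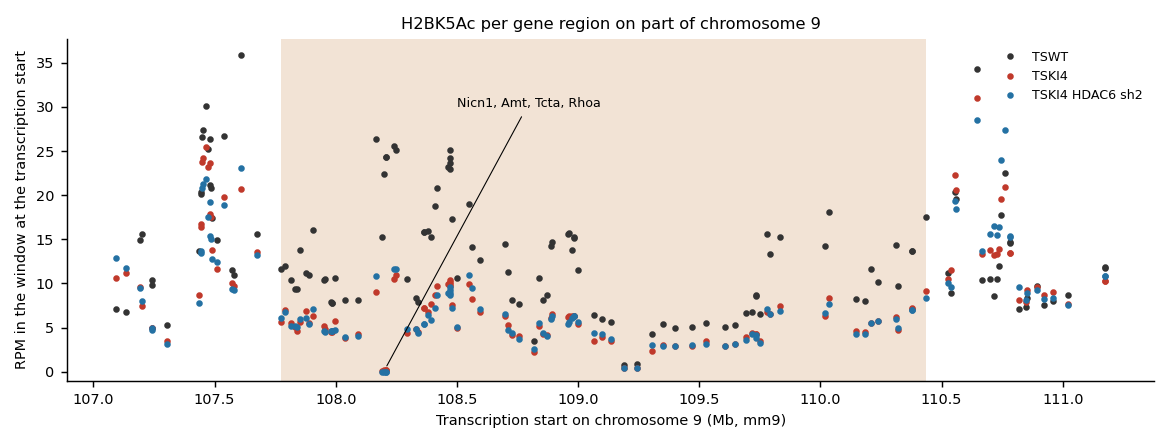
H2BK5Ac (RPM, y axis) of each gene window by transcription start on part of chromosome 9 (Mb, mm9, x axis) in TSWT (black), TSKI4 (red) and TSKI4 HDAC6 sh2 (blue). The shaded block runs from the start of Rbm6 to that of Setd2, and the windows of Nicn1, Amt, Tcta and Rhoa reach 15.2 to 24.3 RPM in TSWT and at most 0.218 RPM in the TSKI4 lines.

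Reads on the Y chromosome, looked at after the values were seen, were also nearly absent from the TSKI4 lines. The 9 Y genes with at least 2 RPM in TSWT, such as Uty and Ddx3y, summed to 3214 reads in TSWT, 27 in TSKI4 and 8 in TSKI4 HDAC6 sh2. In RPM these were 0.735% and 0.235% of the TSWT sum. Low-signal windows of the X chromosome had medians of 3.27, 6.59 and 4.14 RPM, against 5.75, 6.18 and 6.27 RPM for autosomal ones. The X-linked genes named above moved in the same directions as these values. Eda2r, Stard8 and Yipf6 passed the rule in TSKI4 against TSWT after centring too (0.87, 0.78 and 0.60), but they lie in the X block described above. Their log2 ratios as deposited (1.78, 1.58 and 1.46) were near the median of that block (1.61, against 0.76 for its neighbours). The centred values therefore do not show a rise beyond that of the block.

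Among the gene lists, replication-dependent histone genes stood lowest in TSKI4. Of 63 measured, 24 fell and 0 rose, with a median of 20.2 RPM in TSWT and 13.1 in TSKI4. Their relative median was −0.40 (percentile 0) and −0.42 after centring (percentile 0, 18 lower). Hist1h4d (24.6 to 13.1 RPM) and Hist1h2bp (11.8 to 6.13) were the lowest, and many of these genes share a cluster on chromosome 13 and overlapping windows. The 24 lower genes lie at 4 of 13 loci, and with 1 value per locus the percentile was 0.11, and 0.01 after centring. Tight junction and polarity genes followed, at −0.26 (percentile 0.49) and −0.20 after centring (0.18), with 9 of 27 lower and 0 higher. Cgn, which encodes cingulin, fell from 25.1 to 13.0 RPM and Pard6b, a polarity gene, from 30.9 to 16.7, while Mal2 (6.61 and 8.35 RPM) and Cldn7 (22.04 and 28.4) did not pass the rule. After centring 4 of the 27 were lower (3 loci), and with 1 value per locus (26 loci) the list stood apart as deposited (2.19) but not after centring (2.67).

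Hox genes stood highest, at 0.29 (percentile 100) and 0.30 after centring (100), with 6 of 35 higher and 0 lower (4 and 0 after centring). These genes form only 8 loci, 4 of them with higher genes, and 1 value per locus gave percentiles of 99.55 and, after centring, 99.9. Hoxd3 rose from 9.41 to 16.3 RPM beside Hoxb13, and Hoxc6 (12.5 and 8.87) and Hoxa2 (25.1 and 18.9) were the lowest, inside the rule. On the chromosomes without a shifted block, where only part of the Hox clusters lies, the relative median was −0.09. Mesenchymal genes were at −0.11 as deposited (percentile 2.01, 3 of 28 lower), with Foxc2 falling from 23.6 to 11.2 RPM and Cyr61 from 29.6 to 16.7. Centring turned this list to 0.13 (percentile 99.2, 0 lower). Sox9 (8.39 and 12.3) and Vim (6.69 and 8.51) were its highest members, inside the rule. Actin cytoskeleton genes were at −0.12 (percentile 21.1, 3 of 28 lower and 1 higher) and −0.17 after centring (1.35, 2 lower and 0 higher). Tpm4, a tropomyosin gene on chromosome 8, fell from 22.4 to 12.8 RPM, Rhoa fell as described, and X-linked Msn, which encodes moesin, rose from 6.19 to 17.2. Tpm4 and Msn did not pass after centring (−0.22 and −0.15). Cell cycle genes were at −0.05 (62.1, 6 of 25 lower) and −0.16 after centring (0.82, 1 lower), with Cdc25a in the chromosome 9 block falling from 15.6 to 6.80 RPM.

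Epithelial regulators were at −0.14 (percentile 8.5) and −0.13 after centring (3.5), with 5 of 25 lower and 1 after centring. Spint1 (25.4 to 13.1 RPM) and Esrp2 (31.8 to 16.8) fell, but not past the rule after centring (−0.39 and −0.29). Adherens junction, desmosome and keratin genes were at −0.07 (56.6) with 5 of 20 lower and 1 after centring. Krt18 (42.3 to 21.3) and Krt7 (34.9 to 19.1), both on chromosome 15, were the lowest. Neither list stood apart. Trophoblast stem cell factors were at −0.06 (52.6) with 4 of 20 lower, including Satb2 (37.8 to 17.8) and Elf5 (55.8 to 35.0), but 0 after centring (Satb2 −0.55, Elf5 −0.27). FGF and ERK response genes were at −0.07 (72) with 2 of 20 lower, Fgfr1 (40.6 to 21.2 RPM), the receptor gene, and Ccnd1 (18.5 to 11.9), and 0 after centring (−0.39 and −0.55). MAP3K4 signalling genes were at −0.01 (87.5) with 3 of 20 lower, including Map2k7 (21.3 to 12.3), a kinase of the JNK cascade. After centring this list was at −0.09 (26.2) with 0 lower, and Map2k7, on chromosome 8, was at −0.22. Extracellular matrix genes stood apart at 0.11 (99.1) but not after centring (0.02, 88.7), and 6 of 27 fell, including the divergent pair Col4a1 and Col4a2 (29.1 to 17.2 each), but 0 passed after centring. Acetyltransferases and chromatin regulators were at −0.04 (86.9), with Dnmt3l falling from 29.3 to 14.5 RPM, Dnmt3b from 27.3 to 15.3 and Dnmt3a rising from 10.5 to 18.3. All 3 are genes of the DNA methylation machinery. Dnmt3l and Dnmt3a passed after centring (−0.89 and 0.68), and Dnmt3b did not (−0.45). Receptor genes stood apart at 0.21 (97.7) but not after centring (0.15, 88.2), and 5 of 287 rose (2 after centring). With 1 value per locus (202 loci) they did not stand apart as deposited either (92.1). Of the markers of other cell types, primitive endoderm was at 0.22 (97.6), fibroblast at −0.07 (1.61) and blood, neural and muscle at −0.12 (2.47), and none stood apart after centring (percentiles 88, 27.3 and 62.8). As deposited, 9 of the 25 lists stood apart, 6 did after centring, and 4 in both settings, among them mesenchymal genes on opposite sides.

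**Figure D4:**
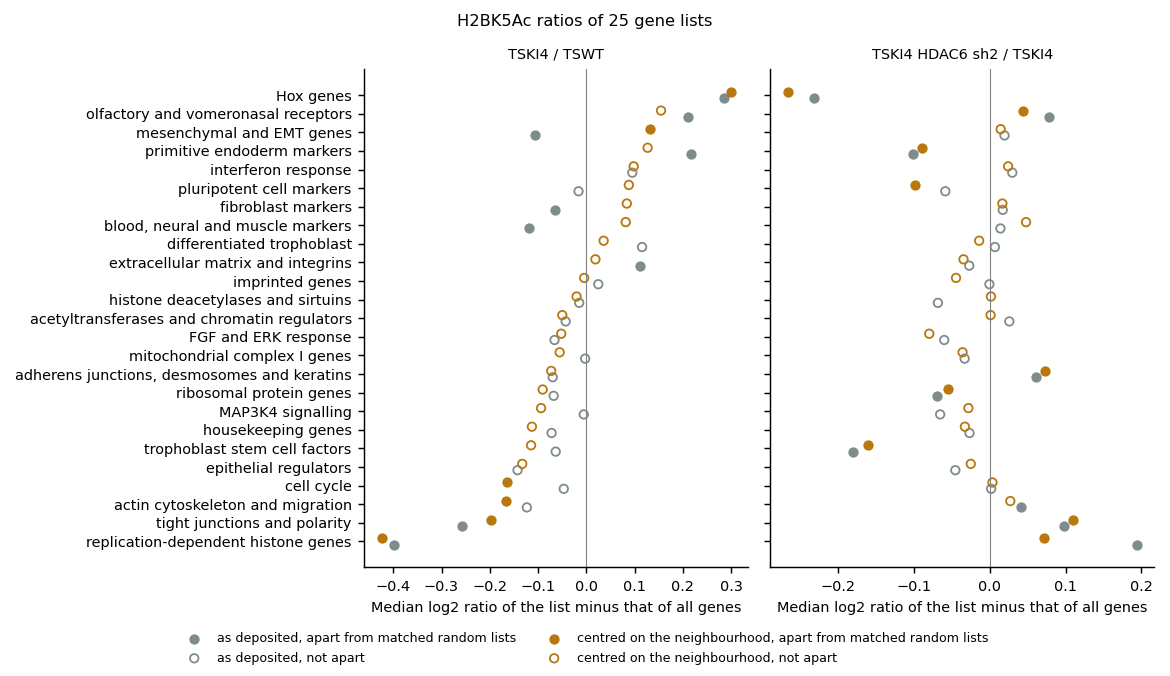
Median log2 ratio of each of 25 gene lists minus that of all genes (x axis) for TSKI4 against TSWT (left) and TSKI4 HDAC6 sh2 against TSKI4 (right), as deposited (grey) and centred on the neighbourhood (brown). Filled points lie outside the central 95% of 10000 matched random lists. Histone genes are lowest on the left (−0.40 and −0.42) and tight junction genes are low on the left and high on the right. Both panels use the same TSKI4 library, so a deviation of that library alone would also give opposite shifts.

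Ratios also fell with signal. From the lowest to the highest of 10 bins of genes by mean signal, the median log2 ratio of TSKI4 to TSWT went from 0.13 to −0.24. The lists and calls above lie on top of this trend, which the matched random lists share. The 1505 lower and 257 higher calls became 779 and 466 with centring by GC content, 156 and 124 with centring on neighbourhood and signal together, and 200 and 73 with centring without the 3 short blocks. Scaling on receptor regions moved the median of all genes from −0.11 to −0.21 and gave 2419 lower and 162 higher genes.

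The second comparison addressed what the HDAC6 hairpin does to H2BK5Ac in TSKI4 cells. Here 287 gene regions (209 loci) were lower and 196 (160 loci) higher in TSKI4 HDAC6 sh2 than in TSKI4. The lower genes off the X chromosome included Ccnjl, Grm6, several Hox genes and Serpinh1, the gene of a collagen chaperone on chromosome 7 (106493885 to 106501749), which fell from 27.8 to 11.1 RPM, 0.398 times TSKI4 (0.368 to 0.431). The higher ones included Ankrd1, Ahnak and Tjp2 on chromosome 19, and Lats2, Amotl2 and Sync elsewhere. Of the calls, 144 of the lower were on the X chromosome and 158 of the higher on chromosome 19.

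Among named genes with a mean of at least 9.95 RPM, the 10 lowest loci held the X-linked Las1l (23.6 to 6.85 RPM), Eda2r (23.6 to 7.26), Yipf6 (21.7 to 6.995), Stard8 (41.9 to 14.6) and Sash3 (29.3 to 12.1). They also held Ccnjl (36.8 to 11.8), Grm6 with Zfp879 (34.7 to 11.4 and 27.6 to 11.6), Hoxb13 (27.7 to 10.4), the kinesin gene Kif26a (16.2 to 6.09) and Serpinh1. After centring the lowest of these were Ccnjl (−1.57), Grm6 (−1.50), Hoxb13 (−1.32), Serpinh1 (−1.24) and Pilra (−1.23, 19.6 to 8.37 RPM). Next were Hoxa10 (−1.21, 19.3 to 7.99), Kif26a (−1.17), the adjacent Hoxd8, Hoxd9 and Hoxd10 (−1.15, −1.11 and −1.04), Tcf15 (−1.12, 19.8 to 8.45) and the focal adhesion gene Parvb (−1.02, 16.99 to 7.38).

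Of the 10 highest under the same limit, 9 were on chromosome 19. They were Ankrd1 (7.97 to 18.0 RPM, a target of YAP signalling), Scgb1a1 (12.3 to 26.7), Ahnak (23.6 to 47.5, a scaffold protein gene), Cfap58 (12.4 to 24.0), Chka (15.7 to 29.7), Atl3 (10.2 to 19.4), Tjp2 (24.4 to 45.3, a tight junction scaffold), Npas4 (8.23 to 15.7) and Ablim1 (12.2 to 22.5). After centring these 9 were at 0.37 to 0.55, inside the rule. Steap2 (7.60 to 16.2) lies near the start of chromosome 5, whose bin from 0 to 10 Mb was at 0.37, and still passed the rule after centring (0.63). After centring the highest under this limit were the adjacent Glt6d1 and Lcn9 (0.89 and 0.86, 7.83 to 14.6 and 9.08 to 16.4 RPM) and Olfr1342 (0.83). They were followed by Sync (0.83, 12.5 to 22.3), Bnip3 (0.79, 10.9 to 18.7), Lats2 (0.77), Lrrn4 (0.76), Mettl5 with Ubr3 (0.76 and 0.72), Gng2 (0.76, 11.3 to 19.9) and Rps6ka5 (0.70, 10.7 to 17.6). Lats2, a kinase of the Hippo pathway on chromosome 14 (58308499 to 58364960), went from 10.7 to 18.5 RPM, 1.73 times TSKI4 (1.59 to 1.89). Zfx was high after centring (0.88) but had a lower value than in TSKI4 (10.4 against 15.7 RPM), as its neighbours were lower still.

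Median log2 ratios were 0.50 on chromosome 19 and −0.65 on the X chromosome, 1.42 and 0.644 times all genes, with low-signal windows at 0.47 and −0.57. All other chromosome medians lay between −0.05 and 0.02, but parts of chromosomes shifted as well. Relative to genes of like signal, chromosome 5 was at 0.37 in the bin from 0 to 10 Mb. It was at 0.26 from 140 to 150 Mb and 0.37 from 150 to 160 Mb, and chromosome 13 was at 0.14 from 20 to 30 Mb. After centring, 126 genes (97 loci) were lower and 33 (30 loci) higher.

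This comparison and the first share the TSKI4 library, so a deviation of that library alone would also move lists in opposite directions. Hox genes stood lowest in this comparison, at −0.23 (percentile 0) and −0.27 after centring (0). Of 35, 10 fell (4 of 8 loci) and 0 rose (11 and 0 after centring), with percentiles of 0.07 and 0.01 at 1 value per locus, and the highest, Hoxa4 (9.25 and 9.65 RPM) and Hoxd1 (8.05 and 8.12), had near-equal values. Trophoblast stem cell factors were at −0.18 (percentile 0.06) and −0.16 after centring (0.32). The 2 of 20 that fell, Rhox6 (13.8 to 5.27) and Rhox9 (10.8 to 4.73), are X-linked and did not pass the rule after centring (−0.57 and −0.38). Ddah1 (20.3 and 26.8) and Id2 (17.4 and 20.3) were its highest members. Primitive endoderm markers were at −0.10 (0.29) and −0.09 after centring (0.415), with Foxa2 falling from 13.1 to 8.31 RPM (−0.58 after centring, inside the rule). Ribosomal protein genes were at −0.07 (0.78) and −0.05 after centring (2.35, but 4.85 with 1 value per locus), and 3 of 80 fell, including X-linked Rps4x (16.1 to 7.13) and Rpl39 (15.8 to 9.54), but 0 after centring.

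Histone genes stood highest as deposited, at 0.19 (percentile 100), and were at 0.07 after centring (100), below both junction lists, but only 1 of 63 passed the rule, Hist1h2be (11.1 to 17.9 RPM), and 0 after centring. With 1 value per locus the percentile was 99.3 as deposited, but 76.9 after centring, not apart. Hist1h4d had 13.1 and 20.1 RPM. Tight junction genes were at 0.10 (99.99) and 0.11 after centring (100), and 2 of 27 rose, Tjp2 and Cldn9, a claudin gene on chromosome 17 (13.0 to 20.501 RPM). Tjp2 did not pass after centring (0.37). Cxadr (20.3 and 16.5) and Scrib (12.7 and 10.6) were the lowest members. Adherens junction and keratin genes were at 0.06 (99.1) and 0.07 after centring (99.7), and 0 of 20 passed the rule. Pkp2 (11.03 and 16.0 RPM), a desmosome gene, and Krt18 (21.3 and 26.4) were its highest members. Receptor genes were at 0.08 (100) and 0.04 (99.8). Actin cytoskeleton genes were at 0.04 (98.3) and 0.03 after centring (95.2), with Msn falling from 17.2 to 5.93 RPM (−0.03 after centring) and Rac1 at 16.9 and 23.0. As deposited, 9 lists stood apart, 9 after centring and 8 in both, and pluripotent cell markers did so only after centring (−0.10, percentile 1.29).

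These lists did not stand apart. Relative medians were −0.05 for epithelial regulators, 0.02 for mesenchymal genes, −0.03 for extracellular matrix, 0.01 for differentiated trophoblast, −0.06 for FGF and ERK response, −0.07 for MAP3K4 signalling, 0.03 for chromatin regulators, 0.00 for cell cycle, 0.02 for fibroblast and 0.01 for blood, neural and muscle markers. Among the highest and lowest members of these lists, those past the rule were Acta2, a smooth muscle actin gene on chromosome 19 (6.53 to 11.3 RPM), and Dnmt3a (18.3 to 11.4). After centring Dnmt3a still passed (−0.59) and Acta2 did not (0.17). In the lists of housekeeping, histone deacetylase and complex I genes, not apart either, the X-linked Pgk1 (14.2 to 8.79 RPM), Hdac6 and Ndufa1 (9.99 to 5.46) fell, but not past the rule after centring (0.17, −0.06 and −0.10). The 287 lower and 196 higher calls became 386 and 103 with receptor scaling, 111 and 42 with neighbourhood and signal centring, and 121 and 33 with centring without the short blocks.

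Across both steps, the question was whether regions lower in TSKI4 than in TSWT were higher again in TSKI4 HDAC6 sh2. Lower in TSKI4 and higher again with the hairpin were 26 genes at 22 loci, 10 of them on chromosome 19. Off chromosome 19 they included Lats2 (22.3, 10.7 and 18.5 RPM in TSWT, TSKI4 and TSKI4 HDAC6 sh2), Amotl2, an angiomotin gene of the Hippo pathway on chromosome 9 (37.0, 16.5 and 27.6), Cldn9 (23.5, 13.0 and 20.501), Sync (29.6, 12.5 and 22.3), Pik3cb (19.8, 12.6 and 20.8), Igf2bp3 (15.7, 9.23 and 15.2), Pdgfa (31.2, 17.6 and 28.0) and Hist1h2be (20.6, 11.1 and 17.9). On chromosome 19 they included Ahnak (43.3, 23.6 and 47.5), Tjp2 (37.2, 24.4 and 45.3) and Ankrd1 (14.6, 7.97 and 18.0). Amotl2, Pik3cb, Igf2bp3 and Pdgfa were picked from the set after their values were seen. The 26 genes were 1.73% of the 1505 lower ones.

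After centring 16 genes (13 loci) met both rules. Of the 26 genes, 12 (46.2%) were among them, including Lats2, Amotl2, Cldn9, Sync, Pik3cb and Igf2bp3, and 0 of the 10 on chromosome 19. Those 10 were at −0.80 to −0.42 in the first step and 0.19 to 0.55 in the second after centring. Fabp3 (40.96, 14.8 and 22.7 RPM) and Eng, the endoglin gene (40.8, 21.3 and 32.4), joined them, with X-linked Zfx and Eif2s3x, which were low and high only relative to their neighbours. Both steps share the TSKI4 library, and simulated counting noise around 3 equal libraries gave 0 such genes in each of 100 runs. Independent lists would share 16.1 genes as deposited and 0.451 after centring. The opposite course, higher in TSKI4 and lower again, was followed by 126 genes (89 loci), 103 of them on the X chromosome, against 4.03 for independent lists. After centring 32 genes (28 loci) followed it, against 0.541, among them Grm6, Ccnjl, Hoxb13, Hoxb9, Hoxa10, Hoxd3, Dnmt3a, Tcf15, Elmo1, Adcy5 and Antxrl. As deposited, the log2 ratios of both steps correlated across genes at −0.24 (simulated noise −0.47), with a covariance of −0.0160 (simulated −0.00183). After centring these were −0.32 and −0.0118. Genes are not independent replicates, and the only TSKI4 library could not be split, so the part due to that library was not separated.

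**Figure D5:**
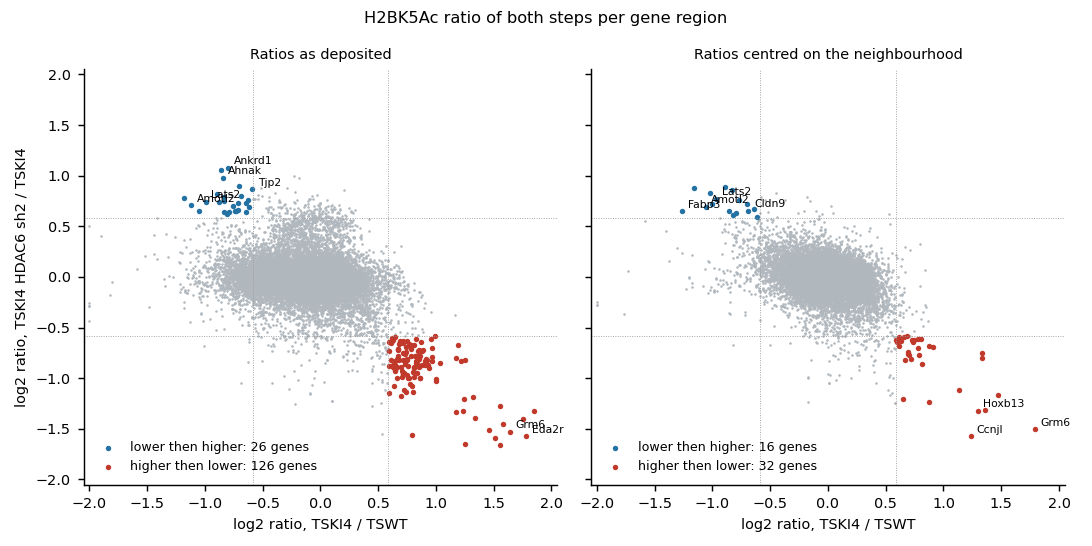
Log2 ratio of TSKI4 to TSWT (x axis) against that of TSKI4 HDAC6 sh2 to TSKI4 (y axis) per gene region (points, drawn at ±2 where beyond), as deposited (left) and centred (right). Dotted lines are the 1.5-fold rule. Blue points fell and rose again (26 genes left, 16 right) and red points rose and fell again (126 left, 32 right).

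The third comparison set the knock-in cells with the hairpin against wild type. H2BK5Ac was lower at 1796 gene regions (1140 loci) and higher at 292 (246 loci). Above the same mean, Sall1 was the lowest again (32.6 to 3.80 RPM), followed by Ackr3, a chemokine receptor gene (16.6 to 4.27), Dusp7, a phosphatase gene of the MAP kinase pathway (35.8 to 10.4), Osgin1 (71.2 to 23.2), Card10 (38.7 to 13.0), Mbtps1 (55.2 to 18.96), Lemd1 (34.0 to 11.4), Serpinh1 (32.6 to 11.1), Bahd1 (29.6 to 10.0) and Nod2 (15.9 to 5.11). The highest were Npas4 (6.995 to 15.7), Pdk1, a kinase of glucose metabolism (10.97 to 23.1), Chrm1 (7.08 to 14.1), Camkk1 (6.97 to 13.7), Oas1f (8.73 to 16.8), Prss44 (8.60 to 16.5), Kank1 (11.6 to 21.6), Ctsf (14.6 to 26.4), Insl6 (8.45 to 15.5) and Tmem98 (11.4 to 20.4). Chromosome 8 held 574 of the lower genes, chromosome 1 held 434, and chromosome 19 held 172 of the higher.

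After centring 231 genes (166 loci) were lower and 60 (51 loci) higher. Among named genes with a mean of at least 9.95 RPM, Sall1 (−2.17), Dusp7 (−1.43), Serpinh1 (−1.38), Naa16 (−1.23), Elf1 with Wbp4 (−1.20 each), Card10 (−1.18), Ackr3 (−1.17) and the adjacent Sorbs3 and Pdlim2 (−1.15 and −1.10) were the lowest, with Ndufaf3, Impdh2, Dalrd3 and Qars (−1.09 to −1.07) in the chromosome 9 block. The highest under this limit were Prss44 with Prss42 and Prss43 (1.13, 0.80 and 0.79), which lie next to that block, Oas1f with Oas1h (1.09 and 0.83), AA543401 (1.03), Pdk1 (0.93), Cd209e (0.90) and Npas4 (0.84), then Lcn4 (0.78), Tmem114 (0.77), Lhfpl5 (0.74) and Rps6ka5 (0.73). Of these, Cd209e on chromosome 8 (10.7 and 12.9 RPM), Prss42, Prss43 and Lhfpl5 did not pass the rule as deposited. As deposited, log2 ratios against TSWT correlated across genes at 0.80 between TSKI4 and TSKI4 HDAC6 sh2, against 0.52 in simulated noise that shares the TSWT library, with a covariance of 0.0867 against a simulated 0.00209. After centring the correlation was 0.75 and the covariance 0.0403.

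Histone genes were at −0.17 (percentile 2.03, 8 of 63 lower) and −0.33 after centring (0, 0 lower), with Hist2h3c1 and Hist2h3c2 falling from 21.9 to 13.96 RPM as deposited. With 1 value per locus the percentiles were 11.2, not apart, and 0.01. Hox genes were at −0.19 (0, 5 of 35 lower) but −0.01 after centring (21.1, 6 lower), and did not stand apart as deposited with 1 value per locus (8.98), with Hoxa3 falling from 19.3 to 11.4 and Hoxa7 from 17.8 to 11.1. Receptor genes were at 0.33 (100) and 0.21 (100). Fibroblast markers were at −0.04 (2.35, but 3.05 when drawn again over loci) and turned to 0.11 after centring (30.7). After centring, trophoblast stem cell factors (−0.27, percentile 1.87), ribosomal protein genes (−0.15, 0.5), imprinted genes (−0.13, 0.485) and tight junction genes (−0.01, 98.4) also stood apart. As deposited these were at −0.26, −0.12, −0.08 and −0.08, not apart. With 1 value per locus imprinted genes (4.22) and tight junction genes (90) did not stand apart after centring. Satb2 (37.8 to 18.6 RPM) and Sox21 (14.8 to 8.58) were the lowest stem cell factors, with Cdx2 at 43.6 and 38.5. Foxc2 fell to 8.004 RPM and Elf3, an epithelial regulator, from 33.1 to 16.6. After centring Foxc2 and Satb2 still passed the rule (−0.67 and −0.59), and Elf3 did not (−0.41). Other relative medians were −0.04 for adherens junction genes, −0.11 for epithelial regulators, 0.01 for mesenchymal genes, −0.03 for extracellular matrix, −0.06 for FGF and ERK response, 0.02 for MAP3K4 signalling, −0.12 for actin cytoskeleton and −0.09 for cell cycle, not apart. The 1796 lower and 292 higher calls became 1309 and 433 with median-of-ratios scaling, 3475 and 62 with receptor scaling (median of all genes −0.13 to −0.30), 875 and 583 with GC centring, 131 and 84 with neighbourhood and signal centring, and 185 and 60 with centring without the short blocks.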

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

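Alternatives planned earlier were median-of-ratios scaling, receptor scaling, the pseudocount, the filter, the size rule, the choice of row, autosomes only and a looser rule for the return to TSWT. GC centring, neighbourhood centring in 3 forms, the chromosomes without a shifted block, lists with 1 value per locus and the interval rule on recovered reads were chosen after the data were seen. Subtraction of input, lists matched on input and both comparisons with input were not run, since the table holds no input values. No paired analysis was possible, because each group held 1 library. Depth limits small differences, with a counting error of about 7% per library at the median region. Of the counts and chromosome medians that answer a comparison, 69 values were the same and 90 moved. Of the values for single genes and lists, 1202 were the same, 265 moved, 46 list results over the comparisons and settings no longer stood apart, 35 newly did and 20 results reversed. With 1 value per locus, 4 of the 22 list results that stood apart as deposited and 5 of 21 after centring no longer did, and 0 newly did. With median-of-ratios scaling and with the mean over the rows of a gene symbol, the counts stayed within 1.5 times, the range being 1179 to 1490 for genes lower in TSKI4 than in TSWT. Counts of genes do not say which genes. Except where the construction of an alternative removes genes or shrinks ratios (filters, size rules, left-out chromosomes, the pseudocount), the cause was not tested.

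In what follows, counts are lower and then higher genes. With the looser size rule (0.32 on the log2 scale, against 0.58) they were 4340 and 1068 for TSKI4 against TSWT, 906 and 946 for TSKI4 HDAC6 sh2 against TSKI4, and 4868 and 1275 for TSKI4 HDAC6 sh2 against TSWT, with 232 genes lower then higher and 352 higher then lower across both steps. With a 2-fold rule they were 112 and 22, 48 and 2, and 170 and 2, with 0 lower then higher and 16 higher then lower. With a pseudocount of 1 median they were 255 and 24, 49 and 7, and 374 and 2, with 1 lower then higher and 17 higher then lower. The relative medians of chromosomes 1, 8 and X in TSKI4 against TSWT were then −0.22, −0.29 and 0.36, and those of chromosomes 19 and X in TSKI4 HDAC6 sh2 against TSKI4 were 0.30 and −0.35.

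With no filter, 868 genes were higher in TSKI4 than in TSWT, 587 were lower in TSKI4 HDAC6 sh2 than in TSKI4, and 404 were higher then lower. Chromosomes 1, 8 and X were at −0.41, −0.49 and 0.76 in the first comparison, and X at −0.54 in the second. Fibroblast markers reversed to 0.0661 in TSKI4 HDAC6 sh2 against TSWT, and blood, neural and muscle markers to 0.0532 in TSKI4 against TSWT. Receptor genes, at 0.14, fell on the low side of their matched random lists (percentile 0.81). With the filter at the 50th percentile, 147 genes were higher in TSKI4 and 128 in TSKI4 HDAC6 sh2 than in TSWT, 66 were higher then lower, chromosomes 1 and X were at −0.40 and 0.73, and X at −0.68 in the second comparison. With autosomes only, 146 genes were higher in TSKI4 than in TSWT, 143 were lower in TSKI4 HDAC6 sh2 than in TSKI4, and 23 were higher then lower.

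Receptor scaling gave 2419 and 162 genes for TSKI4 against TSWT, 103 higher for TSKI4 HDAC6 sh2 against TSKI4, and 3475 and 62 for TSKI4 HDAC6 sh2 against TSWT. GC centring gave 779 and 466 for TSKI4 and 875 and 583 for TSKI4 HDAC6 sh2 against TSWT. It left chromosomes 1 and 8 at −0.39 and −0.45, and put receptor genes, at 0.12, on the low side of their matched lists (percentile 0.985). The interval rule on recovered reads gave 1846 and 350, 353 and 307, and 2098 and 415. With TSKI4 HDAC6 sh2 required only at or above TSWT, or short of it by no more than 0.32 (log2), 49 genes were lower then returned.

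Neighbourhood centring gave 248 and 78, 126 and 33, and 231 and 60 genes, with 16 lower then higher and 32 higher then lower. Without the 3 short blocks the counts were 200 and 73, 121 and 33, and 185 and 60, with 16 and 27. In TSKI4 against TSWT, mesenchymal genes reversed to 0.13 in both forms, fibroblast markers to 0.0840 with the blocks and 0.0833 without, and blood, neural and muscle markers to 0.0817 and 0.0811. In both forms fibroblast markers in TSKI4 HDAC6 sh2 against TSWT reversed to 0.11. With neighbourhood and signal centring the counts were 156 and 124, 111 and 42, and 131 and 84, with 15 and 37, and in TSKI4 against TSWT mesenchymal genes reversed to 0.0464 and extracellular matrix genes to −0.0205. Las1l reversed to −0.24 with neighbourhood centring and to −0.16 with neighbourhood and signal centring. On the chromosomes without a shifted block, which hold fewer genes, the counts were 226 and 27, 58 and 16, and 244 and 14, with 8 lower then higher and 9 higher then lower. There, Hox genes (11 members) reversed to −0.0931 and fibroblast markers (6 members) to 0.0899 in TSKI4 against TSWT, fibroblast markers to 0.19 in TSKI4 HDAC6 sh2 against TSWT, and actin cytoskeleton genes to −0.0013 in TSKI4 HDAC6 sh2 against TSKI4.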

Other observations

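Chosen after their results were seen were the tests of copy number, of a change at active genes alone and of ChIP efficiency, while those of GC content, counting noise and a deviation of the TSKI4 library were set before their results were seen.

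Several gene groups were near the rest of the genome in all 3 comparisons. Differentiated trophoblast genes had relative medians of 0.12 in TSKI4 against TSWT, 0.01 in TSKI4 HDAC6 sh2 against TSKI4 and 0.09 in TSKI4 HDAC6 sh2 against TSWT. Of 26, only Tfeb, the gene of a transcription factor of lysosomes and placental development, passed the rule, in the last of these (36.1 to 20.3 RPM, −0.70 after centring). Hand1, a trophoblast giant cell factor, had 54.0, 48.4 and 36.8 RPM in TSWT, TSKI4 and TSKI4 HDAC6 sh2. Histone deacetylases and sirtuins were at −0.01, −0.07 and −0.04, and besides Hdac6 only Hdac4 passed the rule (29.6 to 17.1 RPM in TSKI4 HDAC6 sh2 against TSWT, but −0.21 after centring). Hdac5 had 32.2 and 21.3 RPM in TSWT and TSKI4, inside the rule. Interferon response genes were at 0.10, 0.03 and 0.16, with Bst2 on chromosome 8 lower in TSKI4 (30.1 to 18.5) and Ifit2 and Ifit3 on chromosome 19 higher in TSKI4 HDAC6 sh2 than in TSWT (5.94 to 10.7 and 5.57 to 10.2). After centring these 3 were at −0.12, 0.17 and 0.18, inside the rule.

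Imprinted genes were at 0.02 and −0.00 in the first 2 comparisons, with 3 of 21 lower in TSKI4 as deposited, among them Grb10 (21.5 to 12.8 RPM) and Nespas (18.3 to 10.5), and 0 after centring (Grb10 −0.31, Nespas −0.44). Sfmbt2, an imprinted gene of the placenta, fell from 37.6 RPM in TSWT to 20.6 in TSKI4 HDAC6 sh2 (−1.03 after centring). Housekeeping genes were at −0.07, −0.03 and −0.09, with B2m (17.7 to 10.2) lower and X-linked Pgk1 (8.89 to 14.2) higher in TSKI4, neither after centring (−0.20 and −0.13). Ribosomal protein genes were at −0.07 in TSKI4 against TSWT. Mitochondrial complex I genes were at −0.00, −0.03 and 0.03, with Ndufs2 on chromosome 1 lower in TSKI4 (29.0 to 14.7, but −0.50 after centring). Pluripotent cell markers were at −0.02, −0.06 and −0.05, and of 15 only Lefty1 passed the rule, in TSKI4 HDAC6 sh2 against TSWT (20.6 to 11.3, but −0.26 after centring). Primitive endoderm markers were at 0.09 and blood, neural and muscle markers at −0.10 in TSKI4 HDAC6 sh2 against TSWT.

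The medians of chromosomes 1, 8, 19 and X shifted between the libraries, though the X chromosome was not uniform in TSKI4 against TSWT. Low-signal windows shifted by at least 0.904 of the shift of the tested genes in all 5 cases, which argues against a change of H2BK5Ac at active genes alone (the same 0.904). Centring by GC content left at least 0.959 of each shift, which argues against GC bias. A different copy number of these chromosomes in the cell lines may therefore account for the shifts. Differences in DNA between the lines may also underlie the near absence of Y reads and the short blocks on chromosomes 9, 14 and X. They may also leave the windows at Rhoa empty. Receptor regions kept medians of 6.27 and 6.60 RPM in TSKI4 and TSKI4 HDAC6 sh2, against at most 0.218 RPM in the windows at Rhoa. That argues against a change of the mark alone at these windows. The input library was of TSWT alone, so it could not show copy number in the TSKI4 lines, and it has no values in the table. No biological explanation by the groups was tested.

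High-signal regions were lower and low-signal regions higher in TSKI4 than in TSWT. On the chromosomes without a shifted block the difference between the top and bottom bins was 1.08 times that over all chromosomes. It was also 1.08 times without the 51 tested genes of the short blocks on chromosomes 9 and 14, which these chromosomes include. Both argue against copy number differences of the left-out chromosomes and of these short blocks as the whole cause. Chromosome 3 was kept, though its bins from 90 to 150 Mb were at −0.27 to −0.11 relative to genes of like signal. The trend was not computed without chromosome 3, so a part from milder shifts of long segments stays open. After GC centring 0.807 of it was kept (0.779 to 0.837 over 1000 bootstrap samples), so GC content accounts for a part at most. TSKI4 HDAC6 sh2 shared the trend against TSWT, with −0.47 between the top and bottom bins of all chromosomes, against −0.37 for TSKI4. On the chromosomes without a shifted block, the ratio of housekeeping to receptor regions in TSKI4 was 0.814 of that in TSWT. A lower ChIP efficiency may give this as well as a lower level of the mark. These cannot be told apart without a spike-in, replicates or input values.

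Among the genes lower in TSKI4 and higher again with the hairpin, counting noise gave at most 0 of the 26 in simulations, which argues against counting noise alone. With a counting error of about 7% per library at the median region, that outcome was foreseeable. Differences between cultures or libraries are not covered by that test. The 10 genes on chromosome 19 kept a median share of 0.819 of their fall after centring (0.745 to 0.926 over 1000 bootstrap samples). Chromosome 19 itself was near all genes in that step (relative median 0.01). This argues against gains or losses of chromosomes or long segments as the cause of the fall. The 10 genes kept 0.405 of their rise (0.337 to 0.491), so a different copy number of chromosome 19 may account for part of it. That includes Ahnak, Tjp2 and Ankrd1. For the rest of the rise, copy number and a change of the mark cannot be told apart without input values of each line. The 16 on other chromosomes kept 0.965 of their fall (0.911 to 1.03) and 1.00 of their rise (0.951 to 1.06), which argues against such gains or losses for these genes as a set. Of them 12 passed both rules after centring. Hist1h2be (0.52), Pdgfa (0.53) and Mir3083 (−0.58) came just under the rule in 1 step, and Lrrn4 on chromosome 2 kept 0.450 of its fall (−0.37). The bootstrap drew the 26 genes 1 by 1 though they form 22 loci, so its intervals are too narrow. Gains or losses of short segments, which centring does not remove, stay open for all 26. After centring, the opposite course held 2.15 times as many loci (28 against 13), so a deviation of the TSKI4 library, or of that culture, may explain both courses. Of the 32 genes of the opposite course, 5 were on the X chromosome. Without the 3 short blocks that course held 27 genes against 16, and the 16 include X-linked Zfx and Eif2s3x. An effect of HDAC6 loss on the genes of either course stays open, since a second hairpin and replicate libraries are missing.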
